A study of Homo sapiens with 15 samples.

How the data were processed

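Total RNA of 5 human neuroblastoma cell lines was measured on 15 oligonucleotide arrays, 3 per line. Per the labels' protocols, cells were grown in medium with 10% fetal bovine serum and counted before isolation, ERCC external RNA controls were added at lysis, and 100 ng of total RNA per sample was labelled with biotin by a 3' in vitro transcription protocol. The values used are the authors' deposited intensity values, 1 per probe set and array, on a linear scale. MAS5 is named per the submitters' processing notes, and its version, the background correction, the normalization and the scale are not given in the sources used here. In the deposited values the median of the ERCC probe sets was nearly equal on all arrays (8.85 to 9.12 on the log2 scale) while the median over all probe sets ran from 51.9 to 126, so the arrays had not been scaled to a common total. Whether the authors used the ERCC probe sets to scale the arrays stays unknown. Such values keep differences in the amount of RNA per spike-in between lines, and a gene can therefore differ between lines because all genes do. Results are given on the deposited scale and, where it mattered, after each array was centred on its median over the tested genes.

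The table held 49494 probe sets. Of these, 45277 named 1 gene in the annotation used here, 1333 named several, 2682 named none and 202 were control probe sets, 100 of them for ERCC transcripts. No gene was named from a probe set with several genes. Probe sets marked _s_at or _x_at can match related transcripts, and they were left out in an alternative. The probe set with the highest mean over the 15 arrays stood for a gene, which gave 18244 genes. A gene was tested when its highest line mean was at or above the median of all values (6.35 on the log2 scale, an intensity of 80.6), and 12721 genes passed. Of these, 12713 had their symbol in the RefSeq gene table of assembly GRCh38.p14, which was used only for names and for the order of neighbouring genes. For all tests the values were transformed as log2(intensity + 1). For arrays, the number per line limits the precision, and dim genes lie near the background, where a fold understates the change.

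Samples were grouped by the cell line in the labels. NGP, BE(2)-C and KELLY were taken as MYCN-amplified and SK-N-AS and SH-SY5Y as not amplified, from general knowledge of these lines. A limma model (version 3.58.1, R 4.3.3) with 1 mean per line was fitted to all 15 arrays with an intensity-dependent prior variance, and all 10 pairs of lines were contrasted. A pairwise difference was called at a Benjamini-Hochberg adjusted p under 0.05 within the contrast and an absolute log2 difference of at least 1. A gene was said to separate the classes when all 6 contrasts of an amplified with another line were called with the same sign, and to mark a line when all 4 contrasts of that line with the others were. A second limma model used the 5 line means as replicates, 3 against 2, with an adjusted p under 0.05 and no fold threshold, because the line is the biological replicate of a class. The spike-in relative level of an array was the median log2 value of the tested genes minus that of the 33 ERCC probe sets above the filter, and was compared between classes by an exact two-sided permutation test over the 5 line means, whose smallest possible p is 0.1.

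Members of 25 gene lists were fixed before the data were examined and tested with camera, a competitive gene set test in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. The genes named were also set by a rule fixed at that point. They were the 12 genes called higher and the 12 called lower between the classes with the largest smallest difference over the 6 contrasts, the 4 higher and 2 lower marking genes of each line with the largest smallest difference over the 4 contrasts, the 2 to 4 called members with the largest mean difference of each list described (1 where only 1 was called) or, where none was called, the 2 with the largest absolute difference given as values, and MYCN, MYC, MYCL, TWIST1, CDK4 and MDM2. Y-linked genes and XIST were left out, and 1 further gene of the rule was not analysed here. Other genes are said to be chosen after their values were seen.

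Differences between neighbouring genes were scanned on centred arrays with a running median over 15 tested genes in reference order, for each line against the mean of the other 4, over 12700 genes. A run was reported where at least 5 neighbouring windows lay beyond the most extreme window of 100 seeded permutations of the gene order. This scan was chosen after seeing the data.

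The calls were tested on simulated data with 200 of 12721 genes changed. The separating and the marking rule each recovered 100% of changes of 1.5 on the log2 scale and called 0 unchanged genes. For these rules the lines were simulated as equal but for the changed genes, with the spread of replicates alone. The 0 was therefore fixed in advance and says nothing about false calls between real lines. For the test on line means, each gene's line deviations were first taken whole from genes of the data, with the class means removed. The test then recovered 0% of changes of 3 and 100% of changes of 6. Such deviations add no error to the class difference, so that setting cannot show the power or the false calls of the test. With a spread independent between genes the test recovered 5% and 65%, with 3 unchanged genes called. In a simulated run of 25 neighbouring genes raised by 2, the neighbour scan called 24 windows inside the run and 0 elsewhere. The genes had been shuffled before the run was added, which removed any real likeness between neighbours. That 0 therefore says nothing about false runs in the real order.

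The alternatives were 3 other scalings (array medians, quantiles, ERCC medians), a floor under low values, no filter and a stricter one, 3 other treatments of a gene's probe sets, a pseudocount of 16, other variance models, other fold thresholds, adjustment over all contrasts, the replicate number as a block, the line as a random block, other summaries of the ERCC probe sets, an estimated correlation in camera, and leaving out each array and each line. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.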

Results

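Expression was profiled on 15 arrays from 5 established human neuroblastoma lines, with 3 arrays for each of SK-N-AS, SH-SY5Y, NGP, BE(2)-C and KELLY. Neuroblastoma is a childhood tumour of the sympathetic nervous system, and MYCN, a transcription factor of the MYC family, is amplified in part of these tumours. The design set lines known to carry that amplification (NGP, BE(2)-C and KELLY) beside lines known to lack it (SK-N-AS and SH-SY5Y), and the study's title names MYCN and transcriptional amplification as its subject. The mean of the arrays' median intensities was 123 ± 3.23 in SK-N-AS, 54.4 ± 2.65 in SH-SY5Y, 76.8 ± 2.98 in NGP, 103 ± 0.381 in BE(2)-C and 68.3 ± 1.37 in KELLY (SD, n = 3 each). Arrays of a line correlated at 0.993 or above over the tested genes and arrays of different lines at 0.892 or below, and 0 pairs of arrays were identical. The 3' minus 5' log2 difference of the ACTB control probe sets was 0.71 ± 0.06 in SK-N-AS and from 0.97 ± 0.07 to 1.23 ± 0.08 in the other lines. For GAPDH it was 0.35 ± 0.03 in SH-SY5Y and from 0.18 ± 0.02 to 0.24 ± 0.05 elsewhere. An effect of RNA quality on the differences between lines was not tested. The labels number the replicates without saying that they came from separate cultures, so p-values over arrays measure only the spread between these samples, which may be technical.

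MYCN and MYC showed opposite patterns over the 5 lines. MYCN stood at 9925 ± 614 in NGP, 13689 ± 526 in BE(2)-C and 9363 ± 163 in KELLY, against 78.8 ± 6.30 in SK-N-AS and 152 ± 30.2 in SH-SY5Y (intensity, SD, n = 3 each). MYC, the founding member of the family, stood at 1788 ± 128 in SK-N-AS and 1746 ± 145 in SH-SY5Y, against 31.6 ± 4.05 in NGP, 81.0 ± 12.7 in BE(2)-C and 30.2 ± 1.72 in KELLY. The class difference, amplified minus other lines, was 6.63 for MYCN (moderated SE 0.84 over lines) and -5.34 for MYC (moderated SE 0.79 over lines) on the log2 scale. These errors rest mostly on a variance shared by genes (69.8 prior degrees of freedom), not on the spread of each gene over the lines. Both genes separated the classes in all 6 contrasts (limma, highest adjusted p = 5.05e-24 for MYCN and 2.53e-21 for MYC). The exact permutation test over lines gave p = 0.1 for each, the smallest that 10 splits of the lines allow. Of the 4 MYCN probe sets, those not used for the gene gave 11222 ± 312 in NGP and 64.3 ± 6.22 in SK-N-AS, 9745 ± 733 and 91.3 ± 5.54, and 361 ± 59.2 and 71.8 ± 10.7. MYCL, the remaining family member, did not separate the classes, with 242 ± 14.6 in NGP and 33.6 ± 4.59 in KELLY.

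**Figure D1:**
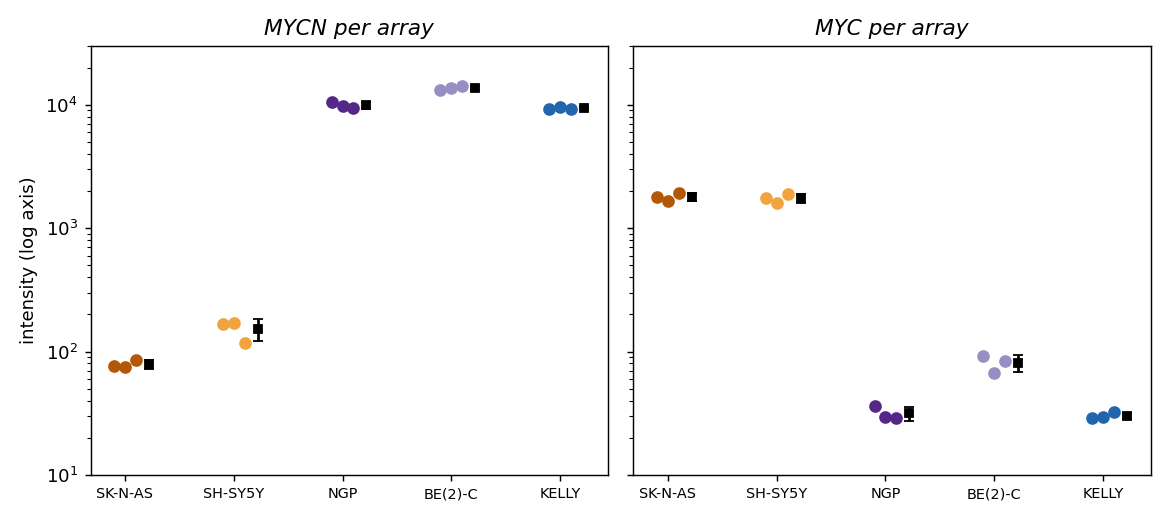
Intensity of MYCN (left) and MYC (right) on each array, on a log axis, by cell line. Circles are arrays, black squares and bars are the mean and SD of 3 arrays. MYCN means lie at 9363 or above in NGP, BE(2)-C and KELLY, where MYC means lie at 81.0 or below.

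The level of cellular RNA relative to the ERCC controls, which were added at lysis after cells had been counted, differed between lines by more than the spread of replicates, with an SD of the line means of 0.55 against a pooled SD of replicates of 0.07 on the log2 scale. The median gene minus the median ERCC probe set was -0.09 ± 0.09 in SK-N-AS, -0.39 ± 0.08 in BE(2)-C, -0.98 ± 0.09 in NGP, -1.22 ± 0.02 in KELLY and -1.37 ± 0.03 in SH-SY5Y (log2, SD, n = 3 each). The highest and the lowest line were both lines without MYCN amplification, and SK-N-AS lay 2.44-fold above SH-SY5Y. The amplified lines differed from the others by -0.14 on the log2 scale (exact permutation test over lines, two-sided p = 0.8, smallest possible 0.1). The sign rested on which lines were included, with 0.51 without SK-N-AS and -0.78 without SH-SY5Y. Measured against 18 hybridization control probe sets, the median gene stood between -2.78 and -2.69 in 4 lines and at -3.17 ± 0.12 in KELLY, while the ERCC probe sets ranged from -2.61 ± 0.12 in SK-N-AS to -1.41 ± 0.06 in SH-SY5Y.

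**Figure D2:**
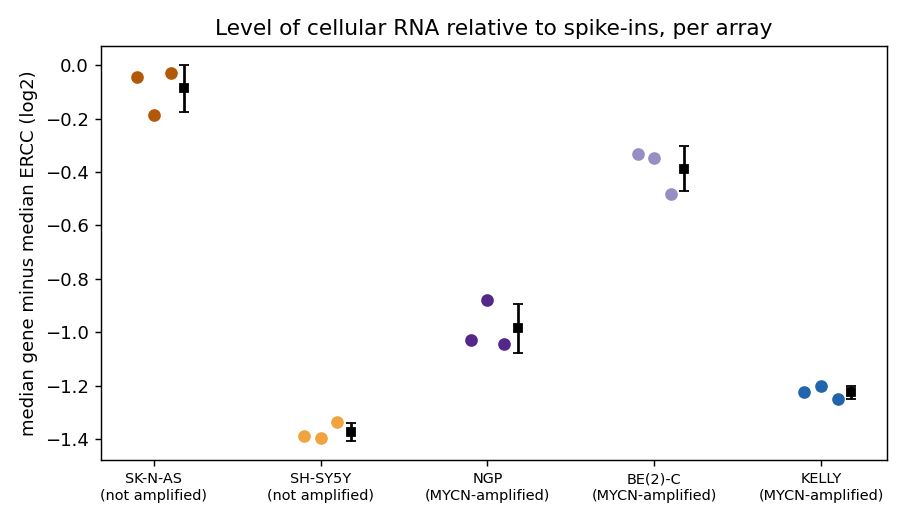
Median log2 value of the tested genes minus that of the ERCC probe sets on each array, by cell line. Circles are arrays, black squares and bars are the mean and SD of 3 arrays. SK-N-AS (-0.09) and SH-SY5Y (-1.37), both without MYCN amplification, are the highest and the lowest line.

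Besides MYCN, the genes that most clearly separated the amplified lines upward included a pair of oncofetal genes. IGF2BP1, an RNA-binding protein of fetal tissue, stood at 2314 ± 116 in NGP, 1276 ± 191 in BE(2)-C and 1392 ± 27.5 in KELLY, against 71.0 ± 3.67 in SK-N-AS and 29.3 ± 3.50 in SH-SY5Y (SD, n = 3 each). LIN28B, which blocks maturation of let-7 microRNAs, stood at 1749 ± 69.5, 1432 ± 58.5 and 1581 ± 29.6 in the same amplified lines, against 27.5 ± 3.81 in SK-N-AS and 242 ± 22.4 in SH-SY5Y. SPOCK3, PELI2, SEMA6A, TRIM9, MECOM, IGDCC4, ZFPM2, IGDCC3 and TRIM59 were also higher, by 2.86 (IGDCC3) to 4.59 (SPOCK3) on the log2 scale. SEMA6A is a semaphorin, MECOM a zinc finger transcription factor and ZFPM2 a cofactor of GATA factors. Lower in the amplified lines were TES, a focal adhesion protein, with 1873 ± 74.5 in SK-N-AS and 1048 ± 51.6 in SH-SY5Y against 44.6 ± 6.08 or less in each amplified line, and CD99, a cell surface glycoprotein, with 5350 ± 385 and 693 ± 46.9 against 48.7 ± 8.85 or less. DNAJC15, NPFFR2, HERC5, GAREM1, FEZ1, GCNT2, PLAGL1, USP44 and BEND7 were lower as well, with class differences from -4.41 (DNAJC15) to -2.24 (USP44). For these 24 genes, MYCN and MYC included, the highest adjusted p over the 6 contrasts was 1.91e-11 (limma, USP44).

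In all, 87 of 12721 genes were higher and 44 lower in every amplified line than in both others. The same rule on centred arrays called 71 higher and 71 lower, which moved the share of higher genes from 66.4% to 50%, and 39 higher and 33 lower genes were called on both scales, all 24 named genes among them. With only 1 line left on the other side, the counts were far larger, 638 higher and 80 lower without SK-N-AS and 374 higher and 1644 lower without SH-SY5Y.

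With the 5 line means as replicates, limma called 25 genes higher and 17 lower in the amplified lines, and 32 of these 42 also separated the classes line by line. Leaving out 1 array moved these counts to between 17 and 42 higher and between 12 and 46 lower. Higher and lower counts were 40 and 41 without SK-N-AS replicate 2, 41 and 46 without SH-SY5Y replicate 1, and 42 and 42 without SH-SY5Y replicate 3, and the lower count was 28 without BE(2)-C replicate 3 and 28 without KELLY replicate 3. More genes were lower than higher with a floor under low values (43 higher and 73 lower), with the mean of a gene's probe sets (47 and 60) and without _s_at and _x_at probe sets (46 and 54). MYCN (adjusted p = 2.72e-07), IGF2BP1 (0.000127) and SPOCK3 (0.000312) were among those higher, and CD99 (1.35e-06), MYC (9.89e-06), TES (1.25e-05) and DNAJC15 (0.000714) among those lower. On centred arrays limma called 0 genes, with 786 at an unadjusted p under 0.05, and after quantile normalization 0 genes, with 808. On centred arrays the differences of these genes changed little and their errors fell. They were 6.67 (SE 0.68) against 6.63 (SE 0.84) for MYCN, -5.30 (SE 0.48) against -5.34 (SE 0.79) for MYC and -5.88 (SE 0.63) against -5.93 (SE 0.81) for CD99. The prior degrees of freedom fell from 69.8 to 2.24, and the adjusted p of MYCN was 0.201. Errors and p-values of this test on the deposited scale thus rested mostly on a variance shared by genes. With equal ERCC medians limma called 10 higher and 9 lower genes.

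In lists of lineage genes the amplified lines stood apart from SK-N-AS and much less from SH-SY5Y. Among 22 neuronal genes the median class difference was 1.62 on the log2 scale, and among 15 genes of catecholamine synthesis and storage it was 1.70. On centred arrays the neuronal genes of the amplified lines lay 3.40 above SK-N-AS and -0.04 from SH-SY5Y, and the catecholamine genes 2.98 above SK-N-AS and 0.30 above SH-SY5Y. The reverse held for 25 genes of mesenchymal matrix and adhesion (-2.54 from SK-N-AS, -0.03 from SH-SY5Y), 23 mesenchymal transcription factors (-1.83 and -0.05), 13 YAP and TEAD targets (-2.48 and -0.21), 22 genes of interferon and innate sensing (-2.35 and -0.08) and 19 of antigen presentation (-2.04 and 0.10). No member of these 7 lists separated the classes on the deposited scale, and the count adjusted over the list alone was also 0. On centred arrays PRPH separated them as higher. By the test on line means, 10 neuronal genes passed when adjusted over the list alone and 0 when adjusted over all genes. In the same order the counts were 5 and 2 for catecholamine genes (CHGA, adjusted p = 0.00762, and SCG3, 0.0292), 5 and 1 for matrix genes (ANXA1, 0.0432), and 6 and 0 for YAP and TEAD targets. They were 4 and 0 for interferon genes, 2 and 0 for antigen presentation and 1 and 0 for mesenchymal transcription factors. CHGA, SCG3 and ANXA1 passed although SK-N-AS and SH-SY5Y lay far apart, as the variance in this test rested mostly on the prior. GAP43, a growth cone protein, stood at 57.6 ± 12.5 in SK-N-AS, 896 ± 32.1 in SH-SY5Y and 1575 ± 29.8 or more in the amplified lines. PRPH, a neuronal intermediate filament, stood at 973 ± 96.2 in SK-N-AS, 26.8 ± 3.03 in SH-SY5Y and 1719 ± 199 or more in the amplified lines (SD, n = 3 each). CHGA and SCG3, proteins of secretory granules, stood at 53.3 and 12.4 in SK-N-AS and at 5858 and 550 in SH-SY5Y. In the lists with the reverse pattern, S100A6 stood at 15184 in SK-N-AS but also at 7985 in BE(2)-C. ANXA1 (8898), MYOF (1063), LATS2, a Hippo pathway kinase (839), IFITM3 (9595), BST2 or tetherin (7877), the immunoproteasome subunits PSMB8 (3197) and PSMB9 (1908), ZFP36L1 (2849) and TWIST2 (499) were bright in SK-N-AS and at 93.9 or less in each other line. With the preset correlation camera called all 7 lists, from adjusted p = 5.69e-19 for the neuronal genes to 3.03e-05 for the mesenchymal transcription factors. None was called with an estimated correlation: neuronal and catecholamine genes had adjusted p = 0.245 with an estimated correlation, matrix, YAP and interferon genes adjusted p = 0.524, antigen presentation adjusted p = 0.592 and mesenchymal transcription factors adjusted p = 0.634. Over all 25 lists camera called 16 with the preset and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. The estimate was -0.064 for LIN28 and oncofetal genes and -0.012 for genes listed for the region of MYCN, below the preset 0.01. Camera did not call these 2 lists either (adjusted p = 0.245 each), so correlation between members does not by itself account for the lost calls.

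**Figure D3:**
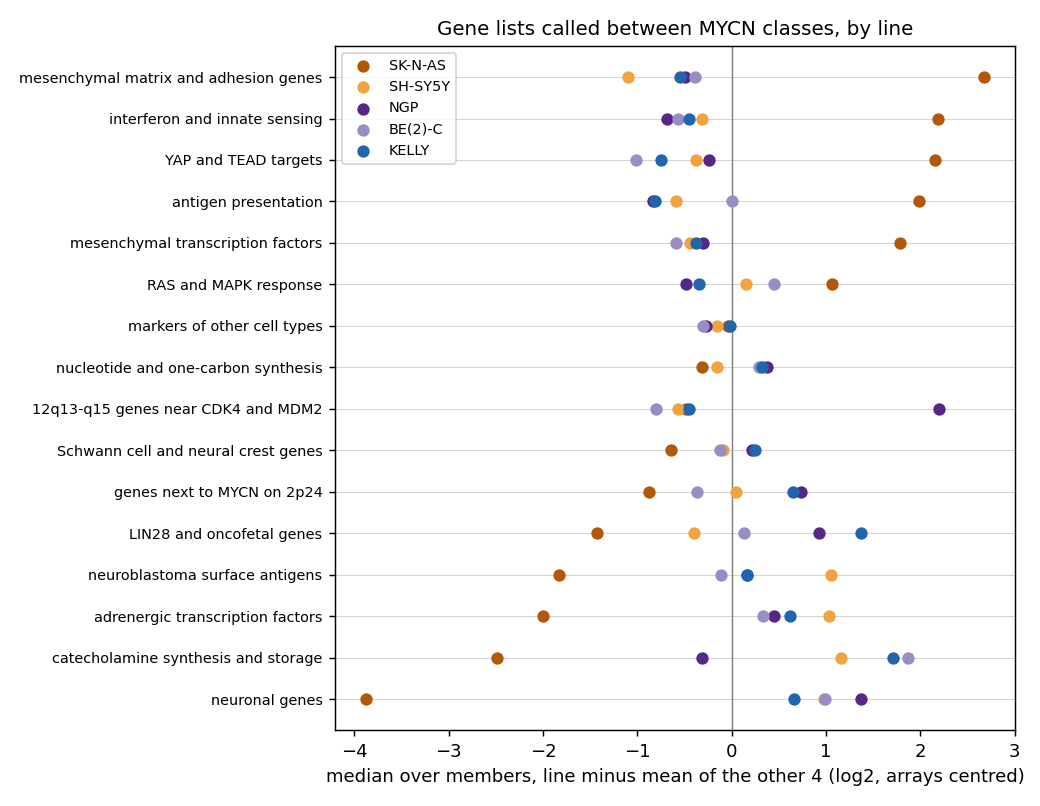
Median over the members of each list of the log2 difference between a line and the mean of the other 4, on centred arrays, for the 16 lists called between the classes with the preset correlation. Each circle is a line. SK-N-AS stands apart from the other lines in most lists, at -3.87 for neuronal genes and 2.68 for mesenchymal matrix and adhesion genes, and NGP at 2.20 for the genes near CDK4 and MDM2.

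Other lists had members that separated the classes. Of 9 LIN28 and oncofetal genes tested, 3 were higher in the amplified lines (IGF2BP1, LIN28B and ARID3B, by 5.10, 4.25 and 2.21) and 0 lower. When adjusted over the list alone 3 were higher, and on centred arrays 2, IGF2BP1 and LIN28B. Camera called this list at adjusted p = 5.20e-07 with the preset correlation and adjusted p = 0.245 with an estimated correlation. Of 17 adrenergic transcription factors, 3 were higher (INSM2, INSM1 and HAND1, by 3.93, 3.76 and 1.81), with smallest pairs of 1.21, 1.09 and 1.10. INSM2 stood at 41.5 in SK-N-AS but 1425 in SH-SY5Y, and INSM1 at 2983 in NGP but 57.3 in BE(2)-C. In this list 3 were higher when adjusted over the list alone and 0 on centred arrays. Camera gave adjusted p = 2.13e-05 with the preset and adjusted p = 0.245 with an estimated correlation. Of 27 genes of nucleotide and one-carbon synthesis, 2 were higher, PHGDH of serine synthesis (1.82) and the mitochondrial folate enzyme MTHFD1L (1.64), again 2 when adjusted over the list alone and 0 on centred arrays. That list had adjusted p = 0.00244 with the preset correlation and adjusted p = 0.817 with an estimated correlation, and its median lay 0.52 above SK-N-AS and 0.46 above SH-SY5Y on centred arrays. SOX2, a stem cell and neural crest transcription factor, was higher by 2.50 among 6 Schwann cell and neural crest genes (adjusted p = 0.0297 with the preset and adjusted p = 0.592 with an estimated correlation). FGFR2 was higher by 2.31 among 18 growth factor receptors, a list that was not called (adjusted p = 0.318).

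Genes listed for the regions of MYCN and of CDK4 and MDM2 were tested as lists, in which 0 members separated the classes on the deposited scale. TRIB2, chosen after its values were seen, separated them as higher on centred arrays, with pairs from 1.03 to 1.89. Among 8 genes listed for the region of MYCN, whose distances from it were not measured here, the median class difference was 1.08 (adjusted p = 0.00038 with the preset and adjusted p = 0.245 with an estimated correlation). On centred arrays the median of this list in the amplified lines lay 1.14 above SK-N-AS but 0.27 above SH-SY5Y. CYRIA stood at 2349 in NGP and 443 in KELLY but at 23.5 in BE(2)-C. GREB1 stood at 627 in NGP, 512 in KELLY, 405 in SH-SY5Y and 96.9 in SK-N-AS. Among 17 genes near CDK4 and MDM2 the median class difference was 0.52. Camera gave adjusted p = 0.036 with the preset, 0.111 on centred arrays and adjusted p = 0.817 with an estimated correlation. Against the mean of the other 4 lines, the median of this list on centred arrays was 2.20 in NGP and between -0.80 and -0.46 in each of the other lines, whose reference includes NGP. AVIL stood at 380 in SK-N-AS and 42.8 in NGP and DDIT3 at 318 in NGP and 52.3 in SH-SY5Y. The remaining called lists, also with 0 separating members on the deposited scale, were neuroblastoma surface antigens (median 0.40, preset adjusted p = 0.00244, adjusted p = 0.245 with an estimated correlation), RAS and MAPK response (-0.38, preset 0.0297, adjusted p = 0.817 with an estimated correlation) and markers of other cell types (-0.04, preset 0.0236, adjusted p = 0.817 with an estimated correlation). Among their members, DLK1 and CD24 were dim in SK-N-AS (52.7 and 61.1) and at 5028 and 4507 in SH-SY5Y. DUSP6 and SPRY1, feedback inhibitors of MAPK signalling, were brightest in SK-N-AS (5843 and 4051). On centred arrays DUSP6 separated the classes as lower, with pairs from -2.99 to -1.29. On centred arrays the surface antigens (adjusted p = 0.389), the markers of other cell types (0.278) and the Schwann cell and neural crest genes (0.0658) were no longer called. The markers of other cell types included the epithelial keratin KRT18 at 8602 in SK-N-AS and 58.1 or less elsewhere, and the leukocyte gene PTPRC at 320 in SK-N-AS and 14.7 or less elsewhere. Ribosome biogenesis (adjusted p = 0.549), cytosolic ribosomal proteins (0.498), polyamine metabolism (0.658), glycolysis and glucose uptake (0.549), cell cycle and E2F targets (0.379), p53 targets (0.549), MYC family and partners (0.41), growth factor receptors (0.318) and MYCN-linked lineage and chromatin regulators (0.916) were not called. PAOX of the polyamine list, chosen after its values were seen, separated the classes as lower on centred arrays alone, with pairs from -2.39 to -1.34. In the last of these the median (0.04) and the mean (-0.01) differed in sign, and TWIST1, which did not separate the classes, stood at 893 ± 86.9 in SK-N-AS, 3884 ± 90.9 in SH-SY5Y and 2760 ± 241 to 5318 ± 372 in the amplified lines.

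SK-N-AS differed most from the other lines. AMIGO2, an adhesion protein, stood there at 7758 ± 285 and at 19.1 ± 1.69 or less elsewhere, ANXA1, an annexin, at 8898 ± 318 against 25.8 ± 3.0 or less, the DNA sensor IFI16 at 9631 ± 381 against 36.6 ± 1.02 or less, and the antiviral protein IFITM3 at 9595 ± 904 against 53.3 ± 10.3 or less. CHGA, chromogranin A of secretory granules, stood at 53.3 ± 8.22 against 5858 ± 491 or more, and DLK1, a non-canonical NOTCH ligand, at 52.7 ± 3.02 against 5028 ± 294 or more. On the deposited scale 1604 genes marked SK-N-AS as higher and 270 as lower, and on centred arrays 714 and 707. The marking genes included 12 of 22 neuronal genes as lower, STMN2, ELAVL4 and DCX among them, and 16 of 25 genes of mesenchymal matrix and adhesion as higher, ANXA1, COL3A1 and CD44 among them (camera, adjusted p = 0.000114 with the preset and adjusted p = 0.152 with an estimated correlation). KRT18 and PTPRC, markers of other cell types, were also brighter in this line (8602 ± 508 and 320 ± 24.6). Camera called 11 lists for this line, among them neuronal genes (lower, adjusted p = 6.62e-24) and catecholamine synthesis and storage (lower, adjusted p = 4.04e-14). With an estimated correlation it called only these 2, each at adjusted p = 0.0188. That test and its correlation rest on the spread of arrays within lines, which may be technical.

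SH-SY5Y was marked by the imprinted gene NNAT at 1117 ± 41.4, against 94.5 ± 11.2 or less elsewhere, by NUDT10 (252 ± 1.95), by the germline PIWI protein PIWIL1 (152 ± 26.5) and by ZNF415 (143 ± 3.12). ASS1, argininosuccinate synthase, stood at 11.9 ± 2.86 against 1706 ± 129 or more in the other lines, and the nuclear corepressor NRIP1 at 7.62 ± 0.569 against 406 ± 35.8 or more. The line had 39 higher and 502 lower marking genes on the deposited scale and 120 and 99 on centred arrays. Camera called 6 lists, and 0 with an estimated correlation (3 at an unadjusted p under 0.05, lowest adjusted p = 0.129 with an estimated correlation).

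NGP was marked by RPRM (1886 ± 116), TMEM163 (767 ± 76.2), the cytochrome CYP1B1 (3479 ± 219) and the neuroendocrine transcription factor INSM1 (2983 ± 183), which reached 176 ± 6.61 at most in the other lines. CYB561, the cytochrome b561 of chromaffin granules, stood at 54.0 ± 7.09 against 3221 ± 204 or more, and the endosomal GTPase RAB4A at 18.7 ± 1.90 against 1095 ± 71.2 or more. CDK4 stood at 13222 ± 1078 against 5913 ± 430 or less, and MDM2, the ubiquitin ligase of p53, at 830 ± 37.6 against 287 ± 8.04 or less. Of 17 genes near CDK4 and MDM2, 10 marked NGP as higher, METTL1 (2671 ± 221), SLC35E3 (3883 ± 133), TSFM (8216 ± 477) and CPM (219 ± 12.4) among them, and the list's median lay 2.05 above the mean of the other lines (camera, adjusted p = 2.93e-11 with the preset and adjusted p = 0.215 with an estimated correlation). The line had 213 higher and 146 lower marking genes, and 236 and 172 on centred arrays. Camera called 9 lists, and 0 with an estimated correlation (4 at an unadjusted p under 0.05, lowest adjusted p = 0.215 with an estimated correlation).

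In the neighbour scan, which was chosen after seeing the data, NGP had 3 runs of higher genes. One ran from AGAP2 to LRIG3 around CDK4 (12 genes, median 2.37 above the mean of the other lines on centred arrays) and one from RAP1B to RAB3IP around MDM2 (9 genes, 2.27). The longest ran over 26 genes from KDM2B to MPHOSPH9, with a median of 2.17 and with 24 of the 26 at their highest in NGP. It held VPS33A (3.20), KNTC1 (3.11), MLXIP (2.95) and DIABLO (2.14), which have different known roles in vesicle sorting, mitosis, glucose sensing and apoptosis. The highest window median in this run was 2.40, against at most 1.28 in 100 permuted gene orders. The ends of the run are set by the windows beyond that bound. Raised genes, chosen after their values were seen, lay past both: RNF34 (2.55) before KDM2B and MTRFR (2.80) after MPHOSPH9.

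**Figure D4:**
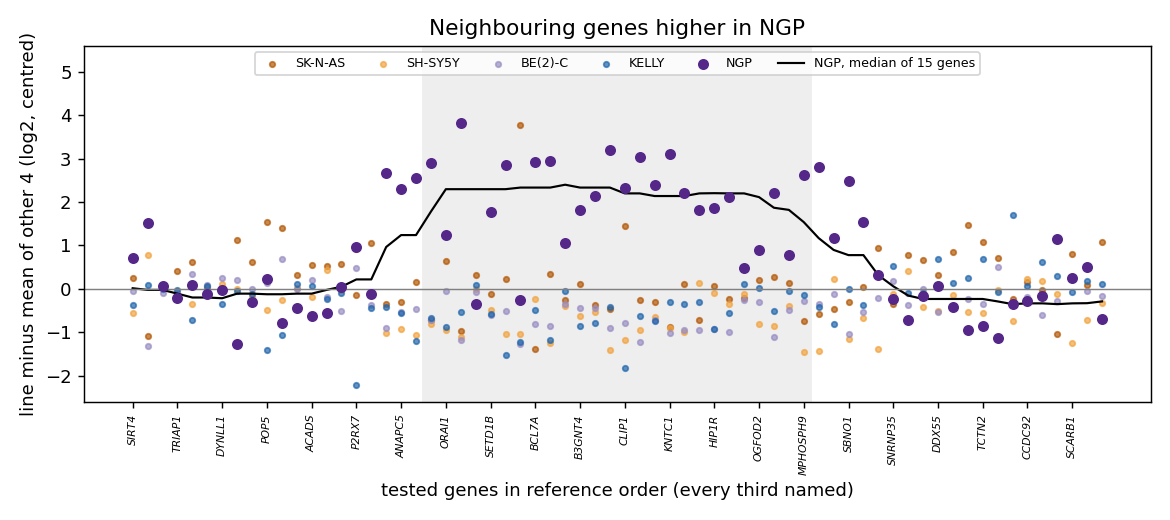
Log2 difference between each line and the mean of the other 4, on centred arrays, for neighbouring tested genes in reference order, with some of the genes named. Circles are genes, the black line is the running median of 15 genes in NGP, and the grey area marks the run of 26 genes from KDM2B to MPHOSPH9, where that median reaches 2.40.

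BE(2)-C was marked by KCNAB1, a potassium channel subunit, at 4011 ± 198, by the sulfotransferase HS3ST2 (2760 ± 238), by ENPP2, autotaxin (3827 ± 239), and by the germline gene TDRD1 (798 ± 88.0). The kinase STK26 stood at 29.8 ± 6.13 against 517 ± 47.8 or more elsewhere, and the transcription factor SOX11 at 52.8 ± 15.7 against 739 ± 39.8 or more. There were 440 higher and 73 lower marking genes, and 141 and 180 on centred arrays. Camera called 9 lists, and 0 with an estimated correlation (2 at an unadjusted p under 0.05, lowest adjusted p = 0.15 with an estimated correlation).

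KELLY was marked by TRIM29 at 1541 ± 43.4 against 29.8 ± 3.65 or less, by the scaffold protein NEDD9 (661 ± 23.8), by SST, somatostatin (517 ± 9.34), and by the protocadherin PCDH19 (279 ± 12.5). CDCA7L stood at 16.7 ± 3.94 against 456 ± 24.2 or more, and the phosphatase CDC14B at 11.7 ± 0.705 against 290 ± 10.9 or more. There were 60 higher and 221 lower marking genes, and 135 and 116 on centred arrays. Camera called 12 lists, and 0 with an estimated correlation (5 at an unadjusted p under 0.05, lowest adjusted p = 0.0965 with an estimated correlation). For all 30 marking genes named for the 5 lines, the highest adjusted p over the 4 contrasts was 1.67e-12 (limma, ZNF415), and all 30 were also called on centred arrays.

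Between pairs of lines, the number of genes that differed ran from 1996 between SH-SY5Y and KELLY, which lay 0.15 apart in spike-in relative level, to 8714 between SK-N-AS and SH-SY5Y, which lay 1.29 apart. Of the latter, 8170 were higher in SK-N-AS, with a median difference over all genes of 1.23 on the log2 scale. Over the 10 pairs the share of calls that were higher in the first line ran from 4.43% to 93.8% on the deposited scale and from 44.6% to 56.3% on centred arrays. On centred arrays SK-N-AS minus SH-SY5Y gave 1468 higher and 1823 lower genes, and the order of the pairs changed, with the fewest genes (1790) between NGP and KELLY and the most (3827) between SK-N-AS and NGP. All 47979 pairwise differences of at least 1 on the log2 scale also had an adjusted p of 0.00997 or less, so the fold threshold alone set these counts.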

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

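All alternatives here were chosen before the data were examined, and the test of which threshold decides the calls was chosen after the result was seen. The MYCN difference kept its sign, and its call in the model over arrays, under each alternative run for it, but its call in the test on line means ended on centred arrays (adjusted p = 0.201) and after quantile normalization (0.212). The fold threshold alone decided the pairwise, separating and marking calls, because 0 of the 47979 differences of at least 1 missed the p threshold. Alternatives that alter only the p-values (variance models, adjustment over all contrasts, the replicate block) therefore could not test the stability of those counts. With the replicate block the counts were 47979 pairwise calls, 87 higher and 44 lower separating genes, and the MYCN difference 6.63. With no fold threshold the block gave 107581 pairwise calls against 108074. The numbers were not taken to pair the arrays: deviations of same-numbered arrays correlated from -0.23 to 0.23 over 30 pairs of arrays, with 5 above 0.1, and 0 arrays correlated best with their own number in every other line.

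Centred arrays gave 71 lower separating genes, 0 higher and 0 lower genes in the test on line means (limma, 786 at an unadjusted p under 0.05), 26521 pairwise calls and 1346 higher marking genes over the 5 lines. Quantile normalization gave 73, 0, 0 (808 at an unadjusted p under 0.05), 26022 and 1372 in the same order. In the test on line means the prior degrees of freedom fell from 69.8 to 2.24 and 2.05, while the MYCN difference was 6.67 and 6.49, so the lost calls do not show that a shift shared by all genes carried these differences. Against these, the deposited scale had 44, 25, 17, 47979 and 2356, and 1212 lower marking genes.

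The test on line means moved under many alternatives. It called 10 higher and 9 lower genes with equal ERCC medians, 43 and 73 with a floor, 47 and 60 with the mean of a gene's probe sets, 46 and 54 without _s_at and _x_at probe sets, 41 and 35 with a robust prior, and 16 and 8 with the line as a random block. It called 6 higher with no filter and 15 higher with a pseudocount of 16. The cause was not tested. Leaving out 1 array gave 17 to 42 higher and 12 to 46 lower genes. Higher and lower counts were 40 and 41 without SK-N-AS replicate 2, 41 and 46 without SH-SY5Y replicate 1, and 42 and 42 without SH-SY5Y replicate 3, and the lower count was 28 without BE(2)-C replicate 3 and 28 without KELLY replicate 3. The other ranges were 6.54 to 6.67 for MYCN, -0.16 to -0.12 for the spike-in relative level, 82 to 90 and 41 to 47 separating genes, 47071 to 48448 pairwise calls, 2309 to 2401 higher and 1186 to 1255 lower marking genes, 16 lists for the class and 46 to 50 list and line pairs.

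Leaving out a line, which leaves fewer contrasts to pass, gave 638 higher and 80 lower separating genes without SK-N-AS, 374 and 1644 without SH-SY5Y, 139 and 73 without NGP, 171 and 146 without BE(2)-C, and 203 higher without KELLY. The test on line means then called 100 higher without SK-N-AS, 171 higher and 628 lower without SH-SY5Y, 9 higher without NGP and 62 lower without BE(2)-C. The spike-in relative level was 0.51 (exact permutation p = 0.5) and -0.78 (p = 0.25) without SK-N-AS and SH-SY5Y.

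With every probe set by itself, more features were tested, with 177 higher and 80 lower separating, 87 and 128 by the test on line means, 109913 pairwise calls, and 5547 and 2383 marking. With no fold threshold there were 445 and 161 separating, 108074 pairwise, and 8860 and 8498 marking genes, and with a threshold of 2 there were 19, 12, 13174, 706 and 301. The stricter filter left 27 lower separating genes. An estimated correlation in camera left 0 of 16 lists for the class (3 at an unadjusted p under 0.05) and 2 of 47 list and line pairs. Of the 16, 4 lost their call on centred arrays, 5 after quantile normalization, 3 with no filter, 1 with the mean of probe sets and 3 without _s_at and _x_at probe sets. Of the genes named by the rule for classes and lines, BEND7 lost its call under the threshold of 2, and TWIST1 gained one without SH-SY5Y.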

Other observations

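The tests of the spike-in relative level, of the gene lists against each line, and of chance order and copy number in the neighbour scan were chosen after the result was seen. The splits of the samples and the scan without shared probe sets were not. The genes in the next paragraph were chosen after their values were seen.

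Each line held some transcripts far below their level in the other 4. Lower than in every other line by at least 3 on the log2 scale, on the deposited scale and on centred arrays, were 48 genes in SK-N-AS, 34 in NGP, 10 in SH-SY5Y, 7 in KELLY and 3 in BE(2)-C. UBB, a polyubiquitin gene, stood at 29.6 in NGP, at 1102 in KELLY and at 11119 or more in the other lines (geometric means of 3 arrays), measured by a probe set that can match related transcripts. TJP1, a tight junction protein, stood at 21.7 in NGP and 514 or more elsewhere. In SH-SY5Y, EBF3, a transcription factor, stood at 21.3 against 278.6 or more, and the phosphatase PTPRK at 14.3 against 297.8 or more. In KELLY the insulin receptor INSR stood at 17.3 against 150.2 or more, and VIM, vimentin, at 155.5 against 1285 or more. The 3 genes in BE(2)-C were STK26, SOX11 and UBE2L6.

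The neighbour scan found 10 runs in all. For 1 of them, 5 genes from FIS1 to PRKRIP1 that were higher in SH-SY5Y, the highest window median without _s_at and _x_at probe sets (0.932) lay inside the permuted maximum (0.971). That run lies within a run that was lower in KELLY, and 12 genes from ORAI1 to VPS33A, lower in SH-SY5Y, lie within a run that was higher in NGP. As each line was set against the mean of the other 4, these are not independent of the runs that hold them, although all 5 genes from FIS1 to PRKRIP1 were at their highest in SH-SY5Y. Of the 12 genes from ORAI1 to VPS33A, 4 were at their lowest there. In KELLY 24 genes from UFSP1 to ARMC10 had a median of -1.31 against the other lines, and 18 of them were at their lowest there. In SH-SY5Y 21 genes from ZNF506 to VSTM2B, nearly all of them zinc finger genes, had a median of 1.28. In NGP 15 zinc finger genes from ZNF805 to ZNF551 had a median of -1.20.

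The spike-in relative level differed between lines far beyond the spread of replicates. The SD of the 5 line means was 7.84 times the pooled SD of replicates. The arrays of a line may share a lysate, and the spread of replicates then holds no error in adding the controls, so this decides nothing about independent errors of that kind, which stay open. With the median gene set against the hybridization controls, SK-N-AS and SH-SY5Y differed by 0.087, although KELLY stood -0.44 from the other lines. A brightness shared by the genes and the ERCC probe sets of an array cancels in the spike-in relative level. The 0.087 therefore does not test the 1.29 between SK-N-AS and SH-SY5Y, and no conclusion is drawn from it. Relative to the 24 poly-A control probe sets both lines were not level. The median gene and the mean of the poly-A controls stood at 8.87 and 9.25 in SK-N-AS and at 7.54 and 8.79 in SH-SY5Y. The median of the ERCC probe sets stood at 8.96 and 8.91 in these lines. The ERCC controls were added at lysis and entered the labelling with the cellular RNA. As far as a different amount of RNA entering the labelling moves both alike, it cancels in the spike-in relative level. The poly-A controls then do not bear on the 1.29. All 3 amplified lines lay below SK-N-AS by more than 2 pooled SDs, but that spread may be technical, so whether MYCN amplification alone sets the level stays open. An error shared by a line's samples, in the cell count or in the amount of controls, cannot be told apart from a true difference in RNA per cell (1.29), because each line has only 1 set of samples to estimate it from.

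The class differences of the mesenchymal, immune and neuronal lists may be differences of SK-N-AS and not of MYCN status. For 8 such lists, adrenergic transcription factors included, the amplified lines' median difference from SK-N-AS on centred arrays had a 95% order statistic interval without 0 in 8, and that from SH-SY5Y in 1, the YAP and TEAD targets (-0.21, from -0.27 to -0.17). These intervals take the members of a list as independent, and each reference is 1 line. Estimated correlations between members ran from 0.09 (adrenergic transcription factors) to 0.92 (antigen presentation), so the true coverage is unknown. Centring shifts the amplified lines down against SH-SY5Y, whose median gene was the lowest (7.54 against 7.76 or more). On the deposited scale YAP1 (21.1) and LATS2 (13.7) were dim in SH-SY5Y and not lower in any amplified line. AMOTL2 was lower in BE(2)-C and KELLY (42.2 and 27.1 against 82.2). That remaining list therefore does not show a class difference by itself, and the question stays open. Of all 16 lists called between the classes, 4 had intervals without 0 against both lines, and besides the YAP and TEAD targets these were nucleotide and one-carbon synthesis (0.52 and 0.46), the genes near CDK4 and MDM2 (0.75 and 0.65) and Schwann cell and neural crest genes (0.74 and 0.14). The genes near CDK4 and MDM2 stood apart in NGP: on centred arrays their median lay 2.20 above the mean of the other 4 lines and 11 members marked NGP as higher, while 0 marked BE(2)-C or KELLY as higher.

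The run from KDM2B to MPHOSPH9 in NGP is a hypothesis for a region of changed copy number, like those known around CDK4 and MDM2. The highest window median of the whole scan in NGP, 2.40, lay in this run. In 100 further permuted gene orders, which had not served to select the runs, the highest window of each order lay between 0.55 and 0.984, which argues against chance order of genes. Without _s_at and _x_at probe sets the highest window median was 2.41, against a permuted maximum of 1.26, which argues against signal shared between related genes. That 92.3% of its genes were at their highest in NGP is what a gain could give, but the run was chosen for its values, and DNA copy number was not analysed here, so a gain cannot be told apart from shared regulation of the region.

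Other splits of the samples gave these counts. Of the 10 ways to divide the 5 lines 3 against 2, 4 gave at least as many separating genes as the MYCN classes (131, highest other 1299), 3 did so on centred arrays (142, highest other 251), 3 in the test on line means (42, highest other 103) and 1 for the gene lists (16, highest other 13). With 10 splits the share cannot fall under 0.05. The split with 1299 genes set SK-N-AS and BE(2)-C, the lines with the highest spike-in relative levels, against the rest, which points to a structure of the samples. On centred arrays, where that level is removed, the same split still gave the most genes (251), so the level alone does not account for it. Of 100 groupings of the 15 arrays into 5 groups of 3, only the real one gave as many pairwise calls (1 of 100, 47979, highest other 12034) or marking genes (1 of 100, 3568, highest other 479). Arrays of a line correlated at 0.993 or above and arrays of different lines at 0.892 or below, so any grouping that mixes lines has a wider spread within its groups. This sets the lines against a spread that may be technical, and whether chance differences between samples of the lines account for these counts stays open. For the list and line pairs called with the preset correlation, 31 of 100 groupings gave at least 47 (highest other 59), so chance is not excluded there.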
